A study of Schmidtea mediterranea with 6 samples.

How the data were processed

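The data are 6 one-colour arrays of a custom Agilent design, 2 for each of the sorted gates X1, X2 and Xins. Per the labels' protocols, mRNA was taken with oligo-dT from sorted cells with a Qiagen kit, amplified linearly from a T7 promoter primer and labelled with Cy3. Groups and replicate numbers were taken from the labels. All arrays lay on 1 slide and were scanned on 1 day, so neither could be tested as a batch.

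The deposited scanner tables hold intensity on a linear scale. Per the file headers, they were made with Feature Extraction 11.5.1.1, and the processed signal is background-subtracted, detrended across the array and replaced by a surrogate where too low. Counted from the per-spot marks in the scanner tables, surrogates made up 55.5% of the spots without controls over the 6 arrays. The authors also deposited a value table of the same arrays. Set against the scanner signal at bright probes (log2 over 8), its columns had slopes of 0.694 to 0.695 per log2 unit, except X2 array 1. The former are close to the slope of a natural log, so the authors' values were read as natural log and converted to log2. The column of X2 array 1 had a slope of 0.719. Over probes well above background on all 6 arrays, it correlated with its scanner signal at 0.987, against 0.998 to 0.999 for the others. Results for X2 from that table rest partly on this column. The column medians were 1.01, 1.16, 0.981, 1.12, 1.14 and 1.31 in the order X1 arrays 1 and 2, X2 arrays 1 and 2, Xins arrays 1 and 2. How the authors normalized and centred that table is not given in the sources used here; the submitters' processing notes name limma only. It served as an alternative.

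Control spots and 11 spots with an outlier mark over the 6 arrays were left out, saturated spots were kept, and spots of a probe were averaged on the log2 scale. The main values are log2 of the processed signal minus each array's 75th percentile. Since at most 28.5% of the probes were well above background on an array, the percentile was taken over the 1914 probes well above background on all 6 arrays. The plan made before the data were examined had the percentile over all probes as the first choice and this one as the alternative; their order was swapped for that reason. A probe was tested where it was well above background on both arrays of at least 1 gate, which left 2910 of 10902 probes. Detection marks are the scanner software's own. Probes with the same sequence were counted as designed, and the number of distinct sequences is printed beside each count.

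Tests were run with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package (version 1.17.8). A single model over all 6 arrays gave the 3 contrasts and the F test, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. The moderated test had 7.08 degrees of freedom in total, 4.08 of them from the prior. Figures were drawn with matplotlib. Where a called probe was above background on no array of the dimmer gate, its fold is a bound: the bright gate's mean against the dim gate's mean of, per array, the higher of the lowest well-above-background signal and the probe's own. Bounds of 1 or less are not counted. Between probes of identical sequence, the SD on an array was 0.148 to 0.260 on the log2 scale. The moderated SD between arrays of a gate, which is drawn towards the prior SD of 0.46, had a median of 0.47.

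Simulated arrays with the real means and residual spread were used to check the fit. For Xins against X1, with 2909 probes of which 200 were changed, 2.94% of changes of 1 on the log2 scale were called, 63.6% of changes of 2 and 97.0% of changes of 3, with 8 calls among the 2709 unchanged probes. For X2 against X1 the shares were 13.2%, 56.1% and 98.5%, with 7 such calls. For Xins against X2 they were 10.3%, 57.6% and 92.4%, with 5. Changes near 1 were thus mostly missed in this setting. In the data many more probes were called, which loosens the adjusted threshold. Calls for Xins against X1 reached down to changes of 1.02 in size, so these shares do not give the power of that contrast.

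Each probe is named by a transcript model, a contig, a strand and a start and end; the genome build is not given in the sources used here. Coordinates are printed as the files give them. The files do not pair these models with gene names, since every description cell is filled with a placeholder. The 18 gene lists fixed before the data were examined (stem cell, cell cycle, polyadenylation, cell type and stress genes among them) could therefore not be matched and were not run. Under the rule fixed for unnamed probes, at most 2 that rose and 2 that fell are given per contrast. They are the largest changes among called probes well above background on both arrays of both gates, with both arrays of a gate above both of the other. The fixed rule asked for this in the brighter gate only. Where 1 array of the dimmer gate sufficed, the rises for X2 against X1 would be at other sites, at 5.87 and 5.73, and the largest fall would be -5.71 at the site named. The other contrasts would keep their sites. Probes with no array above background in the dimmer gate have only bounds and were not ranked. After the values were seen, the rule was narrowed to 1 probe per site, since a second probe of a site already named would otherwise fill a place.

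The position of X2 was set beside 20 simulated data sets each for X2 equal to X1, X2 equal to Xins and X2 as a mixture of their linear signals. Probe switching within a site used limma's diffSplice on sequences averaged over identical probes.

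The alternatives planned were quantile normalization, normexp with an offset of 50 and quantile normalization, the percentile over all probes, median centring, the authors' value table, no filter on dim probes, and only probes above background on all 6 arrays. Further ones were the replicate number or the slide row as a block, an intensity trend with robust estimation, array weights, an added threshold of 1 on the log2 fold change, only the 4 arrays compared, and leaving out each array in turn. Added after the data were seen were the looser filter for named sites, mixtures simulated under other scalings, with the block and with arrays left out, averaging probes of identical sequence, scaling by the kit's E1A spike-in controls, and leaving out probes saturated on any array.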

Results

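Messenger RNA of the planarian flatworm Schmidtea mediterranea, sexual strain, was measured at mapped poly(A) sites in 3 cell populations sorted by flow cytometry. Per the labels, the X1 gate holds stem cells, the X2 gate progenitor cells and the Xins gate differentiated cells. The stem cells (neoblasts) are the dividing cells of the adult worm, and Xins is named for insensitivity to irradiation. Cell type names below stand for these gates, whose purity was not measured here. Each gate was measured on 2 arrays, and all 6 arrays lay on 1 slide. The question of the series is how transcripts with alternative polyadenylation are expressed across the 3 populations, with the array described as one of distal sites. Signals are log2 intensities relative to the 75th percentile of each array, and every mean ± SD below has n = 2 arrays. The labels do not say whether the 2 samples of a gate came from separate animals or sorts, so the p-values measure only the spread between these samples, which may be technical.

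The array carried 10902 probes for 5054 mapped sites. At 433 sites, probes had 2 different sequences, so a probe's 3′ end need not be the end of its site. Many sites were entered through several transcript models, so that the probes held only 5406 distinct sequences. The probes were AT-rich, with a median GC content of 21.7%. Among the 4029 distinct sequences whose site spanned at most 15 nt, 45.8% had the poly(A) signal AATAAA starting 10 to 35 nt from the probe's 3′ end. A further 8.27% had the variant ATTAAA without AATAAA, and 45.9% had neither hexamer in that window. The median distance from the first base of AATAAA to the 3′ end was 23 nt.

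**Figure D1:**
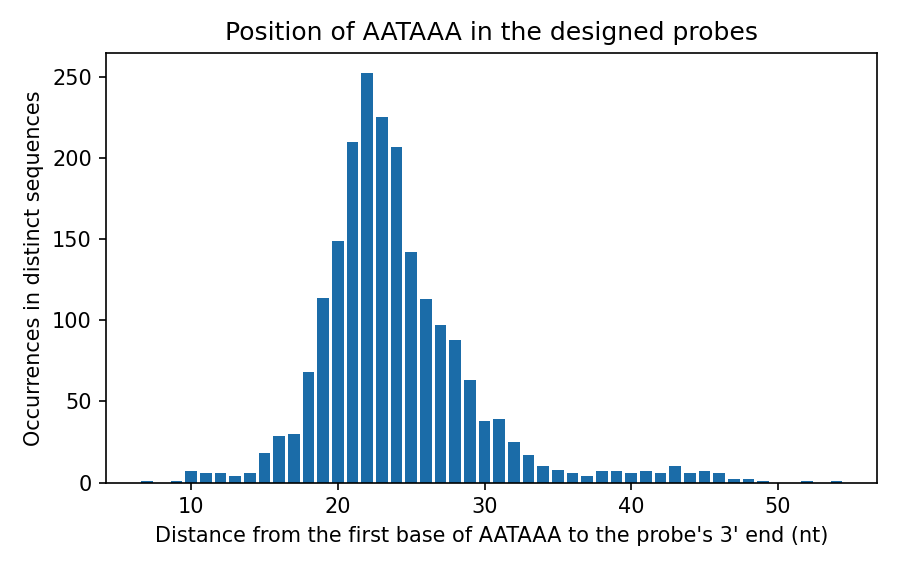
Distance in nt from the first base of AATAAA to the probe's 3′ end (x axis) against the number of occurrences in the distinct sequences of sites spanning at most 15 nt (y axis). The occurrences pile up around the median distance of 23 nt.

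Signal was well above background for 3022 and 2515 probes on X1 arrays 1 and 2, for 3108 and 2717 on X2 arrays 1 and 2, and for 2981 and 2530 on Xins arrays 1 and 2. A total of 1914 probes (1053 distinct sequences) were well above background on all 6 arrays. Sites seen in 1 gate alone were few. They came to 37 probes (30 sequences) on both X1 arrays and no other array, 17 probes (12 sequences) for X2 and 80 probes (62 sequences) for Xins. The comparisons below cover the 2910 probes (1577 distinct sequences) that were well above background on both arrays of at least 1 gate. The number of arrays limits the precision: the 95% interval of a log2 fold change had a median width of 1.10 to either side.

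The profile of X2 lay nearer to X1 than to Xins. Across the tested probes, Pearson's r between arrays was 0.895 to 0.929 for X1 with X2, 0.831 to 0.868 for X2 with Xins and 0.732 to 0.760 for X1 with Xins. Arrays of the same gate correlated at 0.968 (X1), 0.961 (X2) and 0.949 (Xins). Probes are not independent replicates, so these coefficients describe the arrays only. The median absolute log2 fold change over all tested probes was 1.38 between X1 and Xins, 0.94 between X2 and Xins and 0.62 between X1 and X2. In the F test of limma over the 3 gates, 1241 probes (737 sequences, 42.6% of those tested) differed at an adjusted p under 0.05.

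**Figure D2:**
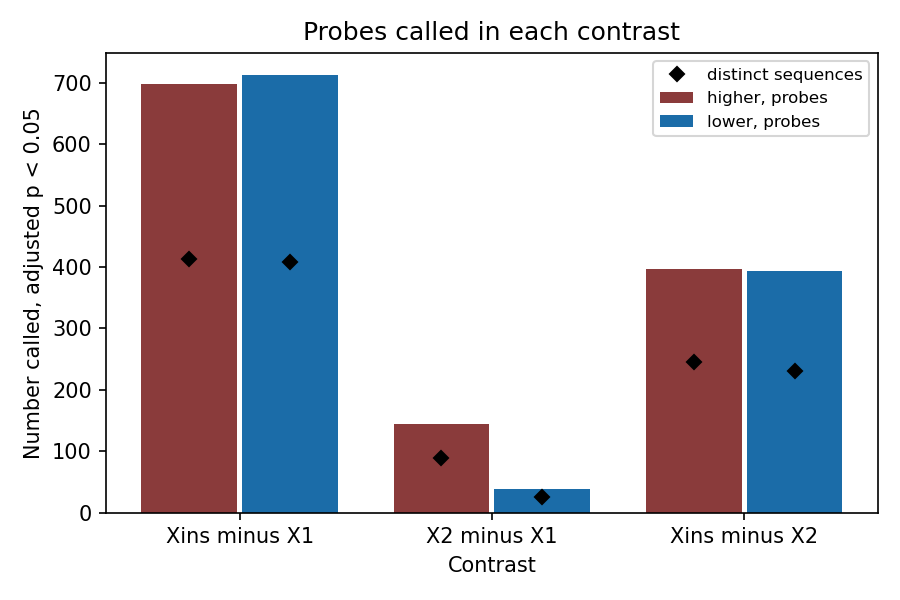
Number of probes (bars) and of distinct sequences (diamonds) higher or lower in each contrast at an adjusted p under 0.05 (y axis), for the 3 contrasts (x axis), with 2 arrays per gate. The bars stand at 698 and 713 for Xins minus X1, 144 and 39 for X2 minus X1, and 397 and 394 for Xins minus X2.

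The comparison of differentiated cells with stem cells is the widest of the series. In Xins, 698 probes (413 sequences) were higher than in X1 and 713 probes (408 sequences) were lower. Of these, 538 of the higher and 555 of the lower probes were above background on at least 1 array of the dimmer gate. Their median fold changes were 5.46 for rises and 3.81 for falls, and 365 and 261 of them differed by at least 4-fold. The files do not pair transcript models with gene names, so sites are given by model and contig. Among probes well above background on all 4 arrays compared, the largest rise was at the site of OX_Smed_1.0.03368 (Contig1945, plus strand, 2917 to 2983), from -3.15 ± 0.45 in X1 to 5.35 ± 1.10 in Xins, a log2 fold change of 8.50 (SE 0.57, adjusted p = 0.000441). This value rests on 1 of the 2 sequences of the site. The other, well above background in Xins only, was at -5.41 ± 0.98 there and gave 2.70, which is not a measured fold change. The site of mk4.000401.10.01 (Contig401, minus strand, 85671 to 85683) rose from -4.67 ± 0.14 to 2.46 ± 0.03, a log2 fold change of 7.13 (SE 0.44). The largest such falls were at the sites of dd_smedV4_21323_0_1 (Contig3562, plus strand, 40966 to 40977), from 1.55 ± 0.29 in X1 to -3.78 ± 0.28 in Xins, and of mk4.000158.09.01 (Contig158, plus strand, 162361 to 162366), from 1.0 ± 0.10 to -4.13 ± 0.14. Their log2 fold changes were -5.33 (SE 0.44) and -5.13 (SE 0.36). The other probes of the mk4.000158.09.01 site carry the same sequence and gave -4.89 and -5.05. After normexp background correction with quantile normalization, the values were 4.32 for mk4.000401.10.01, -3.17 for dd_smedV4_21323_0_1 and -3.0 for mk4.000158.09.01. Of the called probes, 152 of the higher and 143 of the lower had no array above background in the dimmer gate and a fold above 1 against the background limit. For these only a bound holds, with medians of at least 4.09-fold and at least 2.48-fold. The split of higher and lower calls depends on the scaling between arrays and on the model: 49.5% of the calls were higher in Xins here, against 68.1% in the authors' value table, 60.8% when arrays were scaled by spike-in controls, and 46.4% with the replicate number as a block (959 higher and 1107 lower). Without array 1 of X1 the lower calls came to 439, and without array 2 of X1 to 452.

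The X2 gate, labelled progenitor cells, differed from the X1 gate at fewer sites. In X2, 144 probes (89 sequences) were higher than in X1 and 39 probes (25 sequences) were lower. The 97 and 29 of them above background on at least 1 array of the dimmer gate had medians of 7.98-fold and 5.53-fold. The site of dd_smedV4_323_0_1 (Contig532, minus strand, 122619 to 122694) rose from -1.48 ± 0.14 in X1 to 3.67 ± 0.00 in X2, a log2 fold change of 5.15 (SE 0.44, adjusted p = 0.00513). A different probe sequence at the same site, overlapping with an offset of 31 nt, gave 5.13. Overlapping probes are not independent measurements of a site. The signal of this site was 2.60 ± 0.70 in Xins. The site of mk4.021132.00.01 (Contig21132, plus strand, 1622 to 1648) rose by 5.11 (SE 0.74). A different sequence there, overlapping with an offset of 11 nt, gave 4.68. The site of OX_Smed_1.0.00784 (Contig6, plus strand, 49210 to 49219) fell from 0.36 ± 0.66 to -5.03 ± 0.11, a log2 fold change of -5.39 (SE 0.67), with -2.58 ± 1.37 in Xins. The probe of dd_smedV4_60100_0_1, with the same sequence, gave -5.71 (SE 0.75), with 1 array above background in X2. The site of dd_smedV4_21323_0_1 fell here too, with a log2 fold change of -3.44 (SE 0.44). Under spike-in scaling it was at -2.82 and no longer called. After normexp with quantile normalization, the site of mk4.021132.00.01 was at 2.67 and no longer called, and that of OX_Smed_1.0.00784 at -2.49. Of the called probes, 41 of the higher and 10 of the lower have only a bound, with medians of at least 2.39-fold and at least 2.85-fold. The higher calls made up 78.7% here, 52.0% after normexp background correction with quantile normalization, 68.1% with the percentile over all probes, and 93.9% with spike-in scaling. With the replicate number as a block, 535 were higher and 384 lower (58.2% higher), and with the slide row as a block, 218 and 84. The counts rest on each of the 4 arrays compared: higher and lower calls came to 56 and 12 without array 1 of X1, 68 and 10 without array 2 of X1, 62 and 15 without array 1 of X2, and 60 and 18 without array 2 of X2.

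Between progenitor and differentiated cells, 397 probes (245 sequences) were higher in Xins and 394 probes (231 sequences) were lower. The 327 and 282 of them above background on at least 1 array of the dimmer gate had medians of 6.23-fold and 3.33-fold. The site of dd_smedV4_566_0_1 (Contig6828, minus strand, 2795 to 2864) was at -3.42 ± 0.62 in X1, -3.26 ± 0.44 in X2 and 3.38 ± 0.52 in Xins, a log2 fold change of 6.64 over X2 (SE 0.49, adjusted p = 0.00339). A different sequence at that site gave 6.60, but it overlaps the first with an offset of 8 nt. The site of mk4.000002.18.01 (Contig2, plus strand, 461489 to 461505) rose from -5.35 ± 0.45 in X2 to 0.50 ± 1.16 in Xins, a log2 fold change of 5.85 (SE 0.59), and was not well above background in X1. The largest such falls were at the site of mk4.000158.09.01, from -1.11 ± 0.14 in X2 to -4.13 ± 0.14 in Xins, and at that of mk4.027145.01.01 (Contig27145, plus strand, 5550), from 0.23 ± 0.96 to -2.78 ± 0.79. Their log2 fold changes were -3.02 (SE 0.36) and -3.01 (SE 0.66). The latter call ended without array 2 of X2, at -2.34, without array 1 of Xins, at -2.45, and after normexp with quantile normalization, at -1.76. Normexp also gave 2.53 for mk4.000002.18.01 and -1.30 for mk4.000158.09.01. Bounds alone hold for 69 of the higher probes, with a median of at least 3.22-fold, and for 99 of the lower, with a median of at least 1.83-fold. The higher calls made up 50.2% here, 81.5% in the authors' value table, 88.8% with no filter on dim probes, and 39.9% with the replicate number as a block (659 higher and 993 lower). Spike-in scaling left 77 higher and 60 lower. Lower calls came to 129 and 112 without array 1 or 2 of X2, and to 154 and 167 without array 1 or 2 of Xins.

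**Figure D3:**
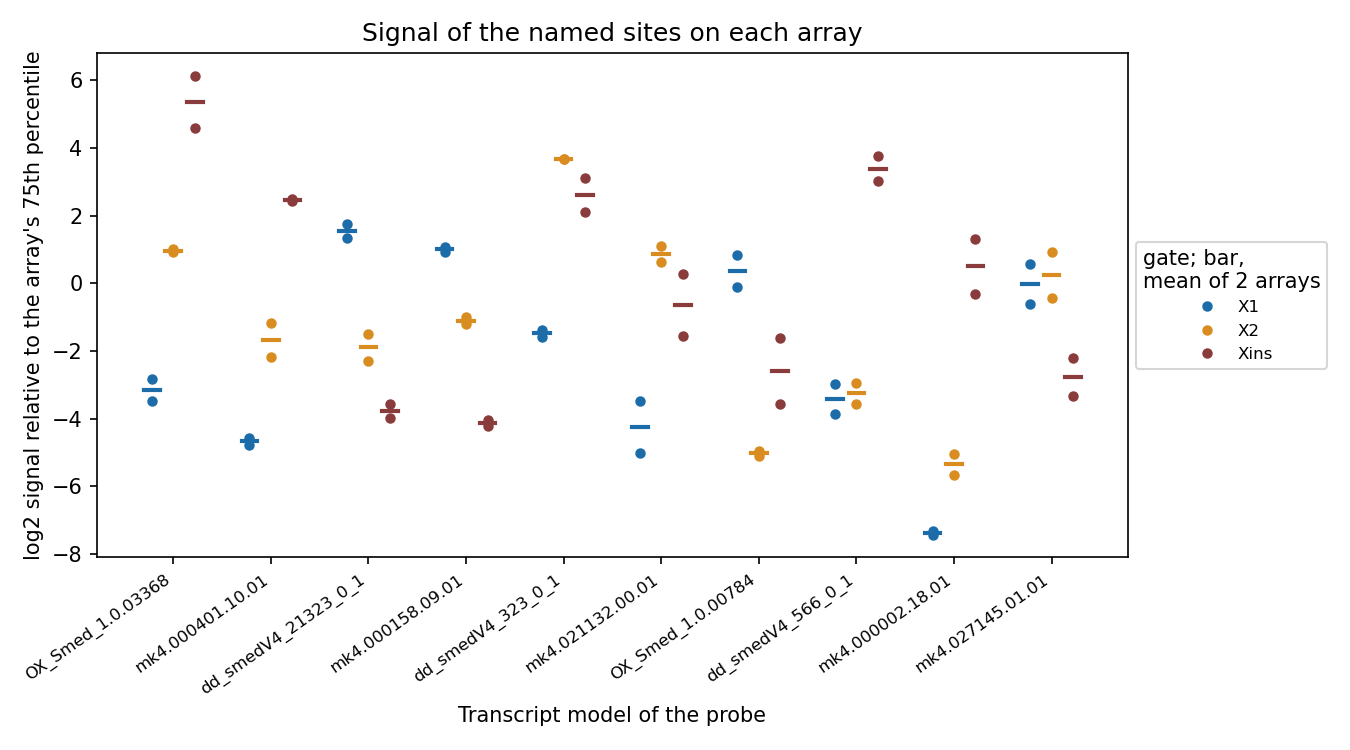
Signal of the named sites on each array, as log2 intensity relative to the array's 75th percentile (y axis), by the transcript model of the probe (x axis). Points are the 2 arrays of X1, X2 and Xins and bars their means. The probe of OX_Smed_1.0.03368 climbs from -3.15 in X1 to 0.97 in X2 and 5.35 in Xins.

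The X2 gate was mostly intermediate at the sites that separate X1 from Xins. Of the 1411 probes called between X1 and Xins, 83.1% had an X2 mean between those of X1 and Xins. The median position of X2 was 0.363 on a log2 scale from 0 at X1 to 1 at Xins. For the same probes, the 3 arrays of replicate 1 alone gave a share of 83.9% and a position of 0.370. The 3 arrays of replicate 2 alone gave 77.3% and 0.344. These figures share arrays with the contrast that chose the probes. In 20 simulations with X2 equal to X1, the median share between was 55.5% and the median position 0.026. With X2 equal to Xins they were 55.1% and 0.972. With X2 a mixture holding a fraction of 0.383 of Xins, the shares were 90.8% to 93.3% and the positions 0.402 to 0.451, both above the observed values. With a fraction of 0.185, fitted to all sequences, the simulated shares were 81.4% to 84.8% of sequences, against 82.7% observed. With a free overall scale they were 84.5% to 89.3%, and with a fixed scale and the replicate number as a block 85.1% to 89.0%, against 77.3% observed in the latter fit. Some sites were set apart in X2: 11 probes (6 sequences) were higher in X2 than in both other gates, and 4 probes (3 sequences) were lower than in both. Of the 11, 5 probes were measured in X1 and in Xins, and the others were not well above background in at least 1 of these gates. With the replicate number as a block, the counts rose to 90 and 63, and with the slide row as a block to 15 and 18. The count of 11 was 12 without array 2 of Xins. It fell to 0 in the authors' value table, to 1 with spike-in scaling, and to 1 without array 1 of X1, 3 without array 2 of X1, 2 and 3 without array 1 or 2 of X2, and 2 without array 1 of Xins. The count of 4 became 2 and 1 without array 1 or 2 of X2, and 11 and 1 without array 1 or 2 of Xins.

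**Figure D4:**
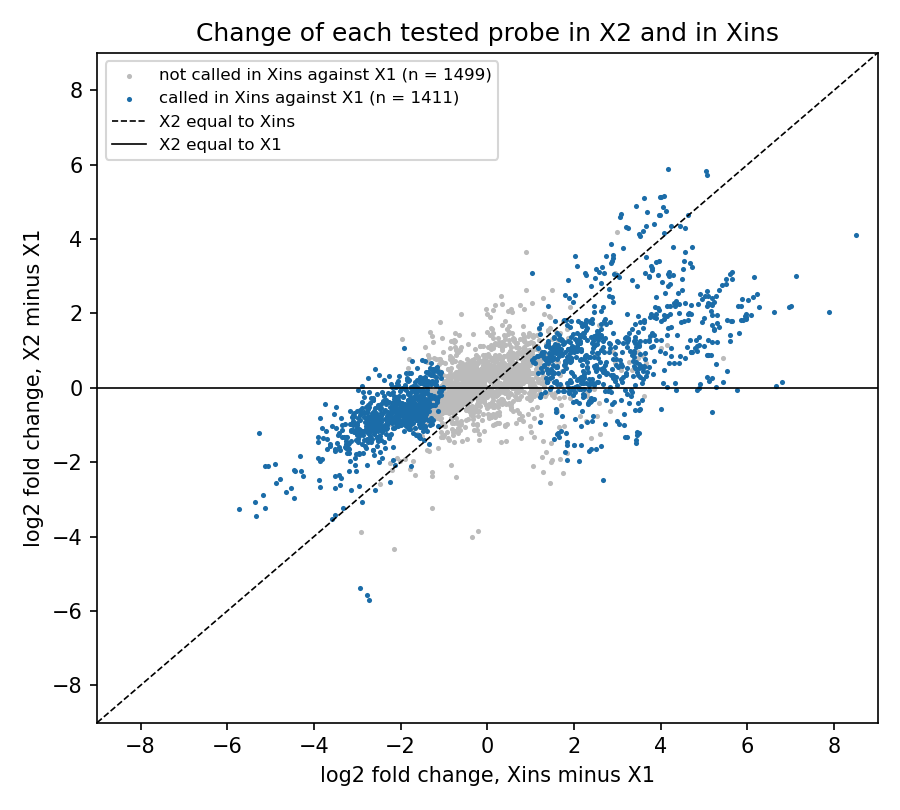
Log2 fold change of each tested probe between Xins and X1 (x axis) and between X2 and X1 (y axis), with probes called between Xins and X1 in blue. Most of the 1411 called probes lie between the horizontal line, where X2 equals X1, and the dashed line, where X2 equals Xins; the median position is 0.363.

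A change of site use within a transcript was testable only in a narrow sense. Among the 9993 transcript models by contig and strand, with isoforms of dd and mk4 models merged, 4 had probes with different sequences at more than 1 site, and 0 of these had more than 1 site among the tested probes. A choice between separate sites of a transcript was therefore not tested. At 232 sites, 2 different probe sequences were tested, and 207 of these pairs overlap with a median offset of 12 nt. Across these sites, the log2 fold changes between Xins and X1 of the paired sequences correlated at r = 0.953, and 97.0% had the same sign. In limma's diffSplice, 1 site differed between its sequences for Xins against X1 at an adjusted p under 0.05, with 12 at an unadjusted p under 0.05. For X2 against X1 and Xins against X2 the counts were 0 and 0, with 9 and 1 at an unadjusted p under 0.05. The called site was that of OX_Smed_1.0.03368, named above. Its other sequence, probed for dd_smedV4_254_0_1, gave a log2 fold change of 2.70 against 8.50, but was not well above background on any array of X1 or X2, so that this fold change is not a measured one. The call was absent when only probes above background on all 6 arrays were tested, and when any array of X1 or X2 was left out.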

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

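The named sites kept their direction in each alternative in which they were tested, and 258 of 263 such values stayed past the threshold. The site of mk4.000002.18.01 was not tested where all 6 arrays had to be above background. The 5 not past it were mk4.021132.00.01 for X2 against X1 after normexp (log2 fold change 2.67), dd_smedV4_21323_0_1 for X2 against X1 under spike-in scaling (-2.82), and mk4.027145.01.01 in the settings given with it above. After normexp, 8 of 12 named log2 fold changes shrank by a factor over 1.5. Under each other alternative, 0 moved by such a factor. Much of this stability, and of the kept directions, was fixed in advance. The named sites were chosen from these same data as the largest called changes, with both arrays of a gate above both of the other. Leaving out an array could therefore not reverse their direction. The replicate block, array weights, intensity trend, added fold threshold and probe filters gave the same fold changes as the main fit. The cause of the changes below was not tested except where named. Averaging of identical probes, spike-in scaling and leaving out saturated probes were chosen after the data were seen. Shifts of each tested probe's log2 fold change from the main fit had medians of -0.19, -0.11 and -0.10 under quantile normalization (Xins against X1, X2 against X1, Xins against X2). In the authors' value table these medians were 0.50, 0.12 and 0.34. Under spike-in scaling they were 0.62 for X2 against X1 and -0.64 for Xins against X2. With the percentile over all probes the median was -0.14 for X2 against X1.

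After normexp, 463 probes were higher in Xins than in X1, 65 higher and 60 lower in X2 than in X1, and 817 differed by the F test; the X2 position was 0.345 and 0 probes were lower in X2 than in both other gates. With the percentile over all probes, 74 were lower in X2 than in X1, the position was 0.386, and 16 were lower in X2 than in both. In the authors' value table, 364 were lower in Xins than in X1, 94 higher in X2 than in X1, 88 lower in Xins than in X2, and 0 higher in X2 than in both. With no filter on dim probes, where more tests were adjusted for, 331 were lower in Xins than in X1, 89 higher and 22 lower in X2 than in X1, 36 lower in Xins than in X2, 760 differed by the F test, and 1 was higher in X2 than in both.

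Fewer probes entered when all 6 arrays had to be above background: 389 higher and 441 lower for Xins against X1, 62 and 20 for X2 against X1, 205 and 233 for Xins against X2, 716 by the F test, 6 higher and 1 lower in X2 than in both, a position of 0.383, and 0 sites with a switch. Averaging probes of identical sequence, which also leaves fewer tests, gave 396 and 389, 82 and 24, 243 and 221, 713 by the F test, and 6 higher in X2 than in both. Spike-in scaling gave 401 and 258, 77 and 5, 77 and 60, 569 by the F test, and 1 higher and 0 lower in X2 than in both. Quantile normalization gave 2 sites with a switch.

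The 2 replicate numbers were not tied to a shared animal or day by the labels. Replicate differences correlated across probes at 0.604 (X1 and X2), 0.487 (X1 and Xins) and 0.440 (X2 and Xins). With the replicate block, 1107 probes were lower in Xins than in X1, 535 higher and 384 lower in X2 than in X1, 659 higher and 993 lower in Xins than in X2, and 2134 differed by the F test; 77.2% lay between, 90 were higher and 63 lower in X2 than in both, and 3 sites had a switch. With the slide row as a block, 218 were higher and 84 lower in X2 than in X1, and 18 lower in X2 than in both. Slide as a block was not run, with 1 slide only; the gene lists with camera and fry, and the choice of probe per gene, were not run for lack of names.

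Leaving out each array in turn left a gate with a single array, assumed to vary like the others. Counts then ranged from 439 to 709 for lower in Xins than in X1, 56 to 158 and 10 to 52 for higher and lower in X2 than in X1, 112 to 308 for lower in Xins than in X2, 1 to 12 and 1 to 11 for higher and lower in X2 than in both, and 0 to 1 for sites with a switch. The X2 position ranged from 0.333 to 0.406.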

Other observations

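All tests here were written down before their results were seen, except that the sequence-level mixture count, its repeats under other scalings, with the replicate block, among measured members and with arrays left out, the bootstrap intervals and the interval of the pair correlation were added afterwards.

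The replicate 1 array was brighter than the replicate 2 array in every gate. The 75th percentile of detected probes differed by 1.11 on the log2 scale in X1, 0.70 in X2 and 0.95 in Xins. If scanner gain or hybridisation of the array were the cause, the E1A spike-in controls, which are usually added to the RNA before labelling, would differ too. They differed by 0.12, 0.26 and -0.31, a mean of 0.0243 against 0.92 for the probes, which argues against such a cause for the whole difference. The amount or quality of the sample RNA stays open as a possible source and was not tested, and no biological explanation was tested.

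Replicate differences were also shared between gates probe by probe, with correlations of 0.604, 0.487 and 0.440. An intensity-dependent response of the dimmer arrays that is common to all probes would be removed by quantile normalization, yet the highest correlation was still 0.562. Quantile normalization would not remove a response near background that differs by probe, so such a response stays open. The GC content of the probe did not follow the difference either (Spearman's rho = 0.00428 over 1577 distinct sequences, permutation p = 0.866). A shared day, sort or batch of animals for each replicate number remains a candidate explanation, which the labels do not record. In X1 and X2, array 1 lay in slide row 1 and array 2 in slide row 2. Row and replicate number can therefore not be told apart in these gates. Both Xins arrays lay in row 2, so row is also partly tied to gate.

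The fold changes between Xins and X1 did not follow GC content of the probe (Spearman's rho = -0.0167 over 1577 sequences, permutation p = 0.507), although the probes were AT-rich.

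A hypothesis was that X2 is a plain mixture of X1-like and Xins-like RNA, with the same fraction at every site. It would give no more probes above both gates than simulated mixtures do. The observed 11 probes exceeded the highest of 20 simulated mixtures, 4, and at the level of distinct sequences the counts were 6 and 4. Below both gates, 4 probes stood against at most 2, and 3 sequences against at most 2. Other scalings gave 9 probes above both (quantile), 11 (normexp), 10 (percentile over all probes), 10 (median centring), 0 (authors' value table) and 1 (spike-in scaling). With the fraction refitted to all sequences, under 7 scalings and with a fixed or free overall scale, the sequences above both gates exceeded the simulated ones in 11 of 14 settings. The exceptions were the authors' value table with either scale and spike-in scaling with a free scale. Below both gates they did so in 6 of 14, and with the main scaling the count of 3 only equalled the highest simulated. With the replicate number as a block, both counts exceeded the simulated ones in 14 of 14, with 17 to 116 sequences above both against simulated maxima of 1 to 25. Only 5 of the 11 probes (3 of the 6 sequences) were measured in X1 and in Xins, against simulated maxima of 4 and 2 among such members. With 1 array left out of data and simulation alike, the count above both exceeded the simulated one in 1 of 6 cases, without array 2 of Xins (12 probes against 4). In the others it was 1 to 3 probes, against maxima of 2 to 7. Below both gates, the probe count exceeded the simulated one without array 1 or 2 of X1 and without array 1 of Xins. It did not in the other cases. All these fits were run without the block. The bound on the probe count was written beforehand and is exceeded, but without the block the count above both gates rests on single arrays. The rule for reading it was changed 3 times after values were seen: it required 5 other scalings, then the block in all scalings, then the bound at both levels, and now also measured members and each left-out array. Without the block, a plain mixture thus stays open, since the outcome turns on the arrays and the scaling. With the block, both counts lay above and the share between the gates below all simulated values in all 14 settings. These settings rescale the same 6 arrays, and the simulated spread was drawn independently for each sequence and array. No array was left out with the block, and the labels do not record whether the replicate numbers mark a shared source. The blocked fits therefore do not decide on a plain mixture. The share between the gates lay below all simulated values in 7 of 14 settings without the block and in 14 of 14 with it (main scaling, fixed scale: 77.3% against 85.1% to 89.0%). A mixture of more than these RNA profiles, or an expression program of X2 itself, stays open too and was not tested.

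Whether sequence elements near the poly(A) site go with the change between Xins and X1 was tested on 732 tested sequences of sites spanning at most 15 nt, in 6 classes, with camera of limma. The adjusted p was 0.920 for each class, and 0.935 with an estimated correlation. The 288 sequences with AATAAA had a median log2 fold change of -0.73 against -0.36 for the others, a difference of -0.37 (95% bootstrap interval over sequences -0.77 to -0.11); 52 were called higher in Xins and 102 lower. The 413 with neither hexamer differed by 0.33 (-0.03 to 0.70). The 187 with ATTTA, an AU-rich element, differed by 0.10 (-0.30 to 0.35), the 19 with a Pumilio-type element by -0.14 (-1.58 to 0.86), the 31 with ATTAAA alone by 0.53 (-1.18 to 1.81), and the 216 mapped to a single position by -0.0049 (-0.39 to 0.44). A p of this size does not exclude a shift, and each interval leaves shifts of over 0.2 open. The bootstrap treats sequences as independent, while camera allows for their correlation, and the AATAAA difference passes only the former.

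Neighbouring sites on opposite strands within 5 kb did not show a shared change between Xins and X1. Over 11 pairs, Pearson's r was -0.211 (permutation p = 0.525, two-sided, interval -0.720 to 0.446) and Spearman's rho -0.382 (permutation p = 0.248), and 6 pairs changed in the same direction. With so few pairs, a moderate positive relation stays open.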
